A study of Streptococcus mutans with 8 samples.

How the data were processed

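Transcript levels of Streptococcus mutans UA159, a lactic acid bacterium of dental plaque, were measured on 8 two-colour spotted DNA arrays. On each array, cDNA of 1 culture was labelled with Cy3 and a common reference with Cy5. Per the labels, 4 arrays carried RNA of cultures grown with air in a shaken flask and 4 carried RNA of cultures grown without oxygen in a sealed jar. All were grown in brain heart infusion broth at 37 °C to an optical density of 0.4, each from a separate culture and RNA preparation. The reference was RNA of the same strain grown in 5% CO2 and harvested at an optical density of 0.6, except that the reference of anaerobic replicate 1 was labelled 0.4. The dyes were never swapped, so a dye bias of a gene is present in every log ratio and drops out only of the difference between groups.

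The deposited spot files held intensity values of both channels, already background-subtracted, as made by TIGR Spotfinder (version 2.2.4, per the file headers of 5 of the 8 files). They also held a deposited fraction per spot, the share of its pixels that were not saturated. The headers named the green image before the red image, which made the first intensity Cy3 (the sample) and the second Cy5 (the reference). Per the labels and the design text of the series, the authors normalized with LOWESS and iterative log mean centring in MIDAS, merged the replicate spots within a slide, and called genes with BRB ArrayTools at p under 0.001. The authors' value table of the series held log2 ratios per spot, with 7791 rows. Set against the spot files it ran in the direction sample over reference, with correlations of 0.927 to 0.988 and slopes of 0.927 to 0.985 on log ratios normalized here with 1 loess curve per array. Its column medians lay between -0.11 and 0.06. The scale and the direction were settled by this match, whereas the exact centring of that table stayed unknown. It was used as an alternative.

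Each array had 10752 spots in 96 print blocks (12 rows of blocks), of which 7792 belonged to 1948 genes with 4 spots each, 2000 were named reserved and 960 were empty. Only 3 of the 8 files listed locus tags and product names. The spot positions were identical in all 8 files, so the same map was applied by spot number to the other 5. Genes are named by the locus tag and product of those files. The reference table of gene names supplied (assembly of another strain) matched 0 of the locus tags, so usual symbols such as gtfB are given as background from gene lists fixed beforehand, and no coordinates are given.

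Spots flagged as bad or with an intensity not above 0 were left out, which kept 95.3% to 99.6% of the gene spots of an array. Log2 ratios of sample over reference were normalized by loess within each print block (span 0.33), each array was centred on its mean, and the spots of a gene were averaged. A gene was tested if measured on at least 3 arrays of each group. The comparison of 4 aerobic with 4 anaerobic arrays was fitted with limma (version 3.58.1, lmFit and eBayes, in R 4.3.3), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are log2, aerobic minus anaerobic, with the moderated standard error (SE). Adjusted p-values of genes are limma's over all 1948 genes unless a list alone is named.

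Gene lists (25, by locus tag, and ribosomal proteins by product text) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares the list with the other genes. The preset of 0.01 treats the members as nearly independent, also where neighbouring genes change together. In fry, the directional test asks only whether the members moved one way on balance. For 6 genes with a missing array the fitted group mean was used in these tests. From the list of CRISPR-associated genes 1 entry annotated as a transcriptional regulator was removed before any value was seen. A set of empty spots gave the background: a gene was counted as above it on an array when the median of its spots exceeded the 95th percentile of that array's empty spots.

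The named genes followed a rule. They were the 8 largest increases and the 8 largest decreases among called genes whose groups did not overlap, up to 3 called members with the largest difference in each list, and 12 genes always named (gtfB, gtfC, gtfD, ftf, spaP, nox, sodA, pfl, ldh, pdhA, vicR and vicK). Groups, tests, lists, this rule and most alternatives were fixed before the data were examined. The alternatives covered 1 loess curve per array, centring on the median without loess, scaling between arrays, an offset of 50, the sample channel alone, the authors' value table, the median of spots, filters on flags, missing arrays and dim genes, limma with trend or array weights, other thresholds, the methods' t-test, a replicate block, a block for the 2 kinds of file layout, and leaving out each array. After the data had been seen 5 alternatives were added: 2 that left out spots whose reference channel was not above the empty spots, 1 that left out the top 2 rows of blocks, 1 that centred on the median after loess per block, and 1 with the sets of arrays formed by the reference channel as a block. The correlations between sets of arrays, the count of which aerobic array lay nearest to the anaerobic mean, and the naming of SMU.1422, SMU.1537, SMU.1538, SMU.574c, SMU.286, SMU.287, SMU.838 and SMU.1869 also came after the data had been seen.

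The scripts were tested on simulated arrays of the same grid and the same spread of genes between arrays for this comparison of 1948 genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, 29.9%, 73.1% and 90.9% were called, with mean estimates of 0.50, 0.98 and 1.92, and 3.62% of the calls were false. The 1 shifted list was called, with 0 others. In the simulation genes varied independently, spot noise was below that of the real arrays, and no rows of blocks lacked signal. The single-gene changes were at most 2 and balanced between up and down. These rates therefore need not hold for the real arrays, where neighbouring genes change together and the largest increases exceed 2. The number of arrays limits the precision. Reserved and empty spots entered no comparison. Same-numbered arrays were checked for pairing. Their deviations from the group means correlated at -0.24 to -0.02, so the replicate numbers were not taken to pair the arrays.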

Results

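The 8 arrays compared S. mutans UA159 cultures grown with air with cultures grown without oxygen, 4 arrays per group, each measured against the same kind of reference RNA (cells grown in 5% CO2). The comparison addressed how the transcript profile of this oral bacterium differs between growth with air and growth without oxygen. Per the labels, the aerobic cultures grew in a shaken flask and the anaerobic cultures in a sealed jar. Oxygen, shaking and vessel thus changed together, and their effects cannot be told apart. The median sample intensity per gene spot ranged from 138089 to 523136 on the aerobic arrays and from 79021.5 to 942128 on the anaerobic arrays. Between 71.1% and 96.0% of genes lay above the empty spots in the sample channel of an array. Log ratios of the aerobic arrays correlated with each other at 0.64 to 0.84 across genes, those of the anaerobic arrays at 0.22 to 0.38.

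Aerobic cultures had higher transcript levels of 9 of 14 genes in the mutacin list, of 3 of 4 genes of the pyruvate dehydrogenase complex, of alcohol-acetaldehyde dehydrogenase and of 9 components of sugar phosphotransferase systems. They had lower levels of the glucosyltransferase gene gtfB, of the 3 genes of the partial citric acid cycle, of 10 of 51 ribosomal protein genes and of 5 of 14 genes in the histidine list. Of 1948 genes tested, 386 differed at an adjusted p under 0.05, with 168 higher and 218 lower in aerobic cultures. At least 2-fold differences were found for 86 of the higher and 27 of the lower genes. In 375 of the 386 genes the 4 values of 1 group all lay above those of the other. This held for 26.2% of all genes tested, against 2.86% expected by chance with 4 against 4. The split of calls depended on the normalization, as 43.5% of calls were higher with loess per print block, 64.6% with 1 loess curve per array (106 higher, 58 lower), 79.4% with median centring only (104 higher, 27 lower), 64.8% with the authors' values (116 higher, 63 lower) and 55.4% with median centring after loess per block (191 higher, 154 lower).

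**Figure D1:**
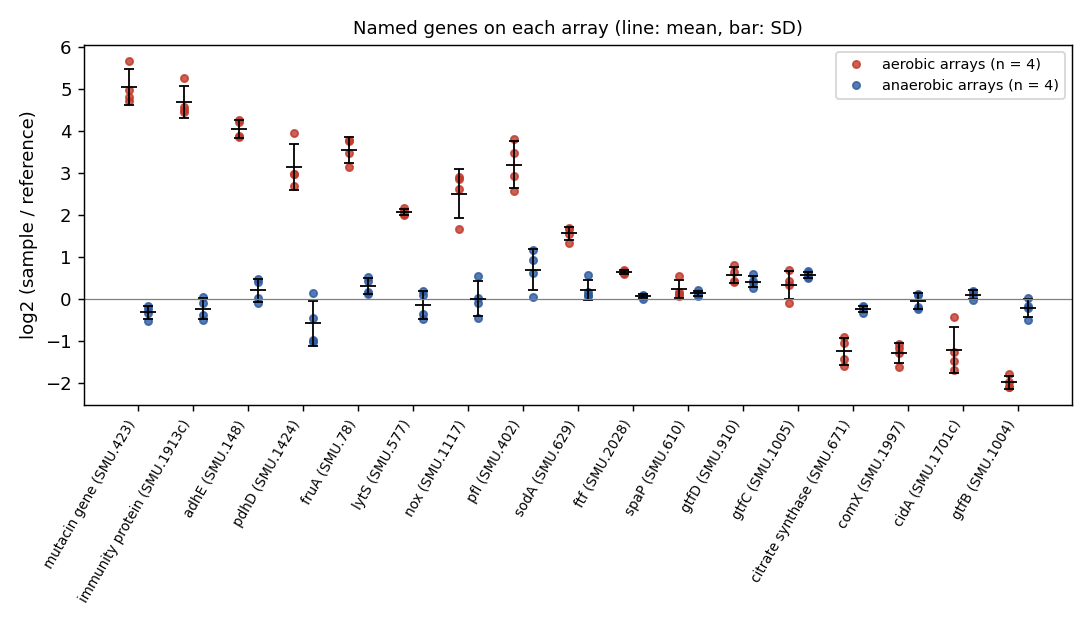
Log2 ratio of sample over reference (vertical axis) of 17 genes on each aerobic (red) and anaerobic (blue) array, with the mean as a line and the SD over 4 arrays as a bar. The aerobic arrays lie above the anaerobic arrays for the genes from SMU.423 to ftf and below them for the citrate synthase gene, comX, cidA and gtfB, while the groups overlap for spaP, gtfD and gtfC.

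Genes of the non-lantibiotic mutacins, small antimicrobial peptides that kill competing bacteria, were among the largest increases. SMU.423 (annotated as a hypothetical protein and listed as nlmD) was 41.1-fold higher in aerobic cultures, with a log2 ratio to the reference of 5.05 ± 0.43 (SD, n = 4) against -0.31 ± 0.16 (SD, n = 4) and an adjusted p of 1.1e-06. SMU.150 (nlmA, of mutacin IV) was 35.6-fold higher, at 4.89 ± 0.23 (SD, n = 4) against -0.27 ± 0.05 (SD, n = 4). The immunity protein gene SMU.1913c was 30.5-fold higher, and the bacteriocin secretion protein gene SMU.1905c 29.3-fold, each with saturated pixels in every spot on 1 array. Of the 14 listed genes 9 rose, 0 fell and 5 were not called, and after adjustment over the list alone 9 were higher and 1 lower. The list shifted upwards (camera adjusted p = 4.7e-10). With an estimated correlation the call ended (adjusted p = 0.104 with an estimated correlation). SMU.286 and SMU.287, annotated as an ABC transporter and its accessory factor, which export such peptides, had log2 differences of 0.11 ± 0.33 (SE) and -0.31 ± 0.37 (SE) and were not called. SMU.286 had reference signal above the empty spots on 4 of the 8 arrays. Genes of hypothetical proteins in the same stretch of locus tags, SMU.1912c, SMU.1903c and SMU.1904c, rose 38.7-fold, 30.7-fold and 29.7-fold. SMU.1903c was above the empty spots on 3 of the 4 anaerobic arrays.

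In the pyruvate dehydrogenase complex, which turns pyruvate into acetyl-CoA, 3 of 4 genes rose, and the list shifted upwards (camera adjusted p = 5.3e-04; adjusted p = 0.089 with an estimated correlation). The dihydrolipoamide dehydrogenase gene SMU.1424 (pdhD) rose 13.3-fold (log2 difference 3.73 ± 0.34, SE), the acetyltransferase gene SMU.1421 (pdhC) 8.95-fold and the E1 alpha gene SMU.1423 (pdhA) 6.89-fold. In anaerobic cultures these 3 were above the empty spots on 1, 2 and 2 of 4 arrays, so their levels there are poorly set and the folds are not exact. The remaining member, SMU.1422 (E1 beta), had a log2 difference of 0.83 ± 0.51 (SE; adjusted p = 0.306). It was printed in an area without signal on 4 arrays, and with spots without signal left out it was called, at 1.93 ± 0.28 (SE; adjusted p = 0.010; the range over all alternatives was 0.010 to 0.999). The neighbouring gene SMU.1425, annotated as the Clp ATPase subunit ClpB, rose 26.4-fold (log2 ratio 4.62 ± 0.35, SD, n = 4, against -0.11 ± 0.07, SD, n = 4), with signal above the empty spots on 3 of 4 anaerobic arrays.

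Among 7 genes of mixed-acid fermentation from pyruvate, 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 1.0e-03; adjusted p = 0.078 with an estimated correlation). Alcohol-acetaldehyde dehydrogenase (SMU.148, adhE) was 14.4-fold higher, at 4.05 ± 0.22 (SD, n = 4) against 0.21 ± 0.28 (SD, n = 4). Pyruvate formate-lyase (SMU.402, pfl) was 5.67-fold higher (adjusted p = 0.0013) and phosphotransacetylase (SMU.1043c) 2.65-fold (adjusted p = 0.0072). SMU.1043c was above the empty spots on 3 aerobic and 2 anaerobic arrays, so its fold is not exact, and its call was lost in 5 of 26 alternatives. Lactate dehydrogenase (SMU.1115, ldh), which makes lactate from pyruvate, was 1.55-fold higher (log2 difference 0.63 ± 0.13, SE, adjusted p = 0.013). Its reference signal was above the empty spots on only 4 of the 8 arrays, and on 1 array every spot held saturated pixels. With spots without signal left out the log2 difference was 0.48 ± 0.40 (SE, adjusted p = 0.450; the range over all alternatives was 0.0074 to 0.999). All 3 genes of the partial citric acid cycle fell: aconitase (SMU.670) 2.08-fold, citrate synthase (SMU.671) 2.02-fold and isocitrate dehydrogenase (SMU.672) 2.02-fold. Aconitase was above the empty spots on 3 of 4 anaerobic arrays. The list shifted downwards (camera adjusted p = 0.0093; adjusted p = 0.208 with an estimated correlation; adjusted p = 0.067 with the sample channel alone). Of 10 glycolysis genes only 6-phosphofructokinase (SMU.1191) was called, 1.26-fold lower (adjusted p = 0.041), a call lost in 17 of 27 alternatives and with saturated pixels in every spot on 1 array, and adjusted over the list alone 0 were called (camera adjusted p = 0.471; adjusted p = 0.746 with an estimated correlation).

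The list for defence against oxygen and its reactive products also holds genes annotated as a regulator, a putative arsenate reductase and 2 hypothetical proteins. Of its 15 genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0021; adjusted p = 0.166 with an estimated correlation). The water-forming NADH oxidase (SMU.1117, nox) rose 5.69-fold, to 2.52 ± 0.57 (SD, n = 4) from 0.01 ± 0.42 (SD, n = 4). The manganese superoxide dismutase (SMU.629, sodA) rose 2.54-fold (adjusted p = 3.9e-04) and alkyl hydroperoxide reductase (SMU.764, ahpC) 2.35-fold (adjusted p = 5.1e-04). The thioredoxin gene SMU.1869 had a log2 difference of 0.14 ± 0.17 (SE, adjusted p = 0.624) and was not called. The glutathione reductase gene SMU.838, at 0.40 ± 0.14 (SE, adjusted p = 0.079), was not called over all genes. It was higher when adjusted over the list alone. In the iron-sulphur cluster assembly list 4 of 5 genes rose (5 adjusted over the list alone; camera adjusted p = 1.0e-03; adjusted p = 0.104 with an estimated correlation), with SMU.250, the NifU-like protein, 1.62-fold, SMU.251 1.53-fold and SMU.248 1.40-fold higher. The calls of SMU.250 and SMU.248 were lost in 16 and 5 of 27 alternatives. In the manganese and iron uptake list 3 of 5 genes rose (4 adjusted over the list alone; camera adjusted p = 0.0019; adjusted p = 0.078 with an estimated correlation). These were the metal-dependent regulator SMU.186 (sloR, 1.67-fold), the manganese transporter SMU.770c (1.66-fold) and the metal-binding lipoprotein SMU.184 (log2 difference 0.68 ± 0.13, SE). SMU.186 was above the empty spots on 2 of 4 anaerobic arrays, so its fold is not exact, and its call was lost in 5 of 27 alternatives.

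Of 29 genes in the list of phosphotransferase systems, which import sugars while phosphorylating them, 14 rose and 2 fell (14 and 4 adjusted over the list alone; camera adjusted p = 2.4e-06; adjusted p = 0.078 with an estimated correlation). Of the 14, 9 are annotated as phosphotransferase components and 5 as enzymes of sugar use. The cellobiose-specific IIB component SMU.1600 rose 15.8-fold and the IIC component SMU.1596 4.02-fold, and the sucrose-specific SMU.1841 (scrA) rose 4.85-fold. SMU.1600 and SMU.1841 were above the empty spots on 1 and 2 of the 4 anaerobic arrays, and in the reference on 5 and 6 of 8, so their folds are not exact. The 2 that fell were the fructose-specific SMU.872 (3.05-fold, adjusted p = 0.045) and the neighbouring kinase gene SMU.871 (2.39-fold, adjusted p = 0.043). Their log2 ratios were widely spread on the aerobic arrays (SD 1.08 and 0.83) and little on the anaerobic arrays (SD 0.15 and 0.05). SMU.872 and SMU.871 are outside the naming rule and were chosen after their values were seen. Of 18 genes for raffinose, maltose and glycogen use, 9 rose and 0 fell, also when adjusted over the list alone. It was the only list whose shift was called by camera both at the preset (adjusted p = 2.3e-07) and at the estimated correlation (adjusted p = 0.046 with an estimated correlation). The glycogen branching enzyme SMU.1539 rose 9.26-fold, the glycogen synthase SMU.1536 6.21-fold and the sucrose phosphorylase SMU.881 (gtfA) 2.38-fold. The genes that rose were SMU.1539, SMU.1536 and those of the adjacent tags SMU.877 to SMU.883. The maltose transporter genes SMU.1568, SMU.1569 and SMU.1570 were not called. Their log2 differences were 0.32 ± 0.18, -0.09 ± 0.20 and -0.06 ± 0.16 (SE), and they were chosen after their values were seen. Of the 9 members not called, 3 were printed in the area without signal on 4 arrays. With spots without signal left out, SMU.1537 and SMU.1538 among these were called, at 2.71 ± 0.37 (SE; adjusted p = 0.015, range over all alternatives 0.015 to 0.972) and 2.68 ± 0.33 (SE; adjusted p = 0.013, range 0.013 to 0.977).

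**Figure D2:**
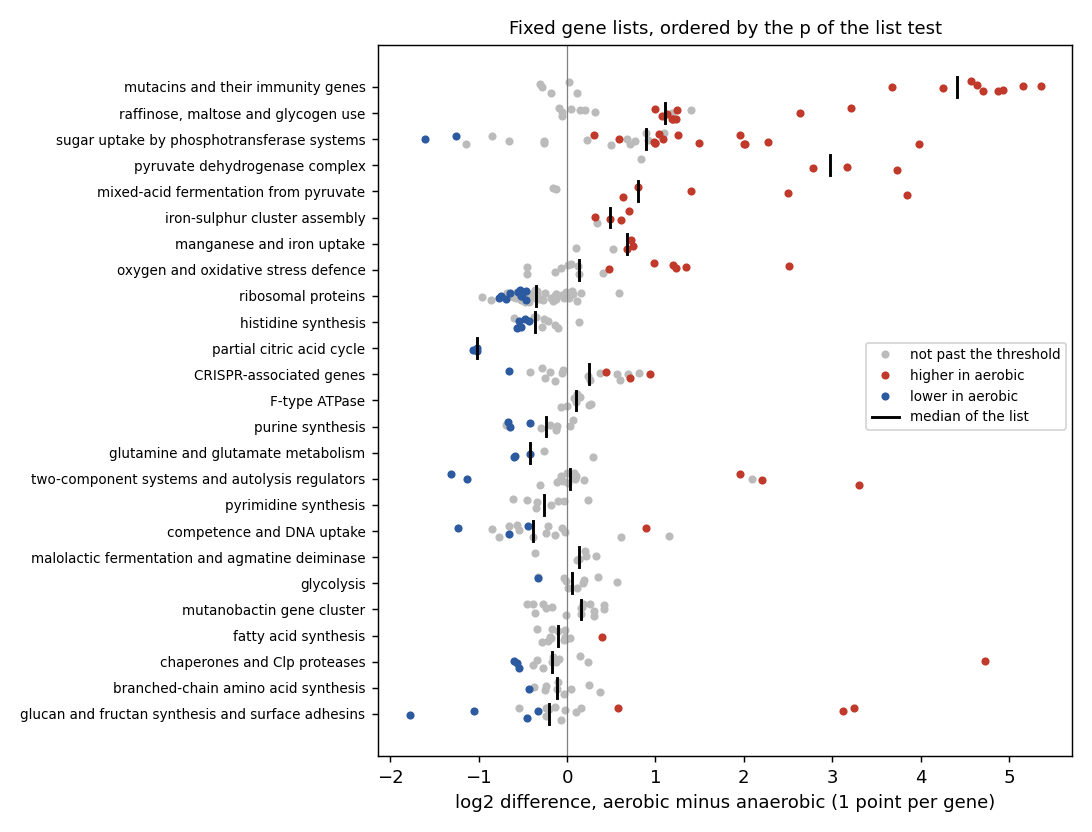
Log2 difference, aerobic minus anaerobic (horizontal axis), of each gene of the 25 fixed lists, coloured by whether the gene was called higher (red), lower (blue) or not called (grey), with the median of each list as a black line. The mutacin list has a median of 4.41 with 9 red points, and all 3 genes of the partial citric acid cycle lie near -1.02.

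Genes in the list of glucan and fructan synthesis and surface adhesins, most of which build, anchor or degrade the plaque matrix, moved apart. Of 17 genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). The camera test gave an adjusted p of 0.971 (p = 0.970 adjusted with an estimated correlation), while fry called the list upwards (fry adjusted p = 0.019). The list's median difference was -0.20 while its mean was 0.11. The glucosyltransferase SMU.1004 (gtfB), which makes water-insoluble glucan, fell 3.44-fold, from -0.20 ± 0.22 (SD, n = 4) to -1.98 ± 0.15 (SD, n = 4), with an adjusted p of 4.4e-05. Its neighbour SMU.1005 (gtfC) had a log2 difference of -0.24 ± 0.16 (SE; adjusted p = 0.345) and SMU.910 (gtfD) of 0.15 ± 0.12 (SE; adjusted p = 0.421). With scaling of the log ratios SMU.1005 passed the threshold at -0.54 (adjusted p = 0.047; the range over all alternatives was 0.047 to 0.997). SMU.1005 had the opposite sign with 1 loess curve and with median centring only, SMU.910 with scaling of the log ratios and with the sample channel alone. The fructan hydrolase genes SMU.78 (fruA) and SMU.79 (fruB) rose 9.46-fold and 8.73-fold, and the fructosyltransferase SMU.2028 (ftf) rose 1.49-fold (adjusted p = 0.0013), with the opposite sign in the sample channel alone. SMU.79 was above the empty spots on 2 of 4 anaerobic arrays, so its fold is not exact. The adhesin gene SMU.610 (spaP) had a log2 difference of 0.10 ± 0.12 (SE; adjusted p = 0.608).

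Among 18 genes in the list of two-component systems and autolysis regulators, 3 rose and 2 fell, and the same numbers resulted when adjusted over the list alone (camera adjusted p = 0.159; adjusted p = 0.388 with an estimated correlation). Fry called this list upwards (fry adjusted p = 0.035). The sensor kinase SMU.577 (lytS) rose 4.63-fold, its response regulator SMU.576 3.87-fold and the membrane protein SMU.575c (lrgA) 9.85-fold, whereas SMU.1701c (cidA) fell 2.49-fold. SMU.574c (lrgB), printed in the area without signal, was called only in 3 of 24 alternatives, at 3.80 ± 0.47 (SE; adjusted p = 0.0068, range 0.0068 to 0.964) with spots without signal left out. SMU.575c and SMU.576 were above the empty spots on 1 and 3 of the 4 anaerobic arrays, and SMU.575c in the reference on 6 of 8, so the fold of SMU.575c is not exact. The response regulator SMU.1517 (vicR) and its kinase SMU.1516 (vicK), which control cell wall and glucan genes, had log2 differences of -0.07 ± 0.24 (SE; adjusted p = 0.860) and -0.07 ± 0.12 (SE; adjusted p = 0.732). In the competence list, of 17 genes 1 rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.446; adjusted p = 0.772 with an estimated correlation). The competence regulator SMU.1997 (comX) fell 2.35-fold and SMU.625 (comEA) 1.58-fold, while the histidine kinase SMU.1916 (comD) rose 1.85-fold. The call of SMU.625 was lost in 8 of 27 alternatives. Of 13 genes in the chaperone and Clp list 1 rose, SMU.1425 described above, and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.587; adjusted p = 0.772 with an estimated correlation), with SMU.83 (dnaJ) 1.52-fold and SMU.80 (hrcA) 1.48-fold lower. These calls were lost in 16 and 17 of 27 alternatives, and SMU.80 had the opposite sign in the sample channel alone. The median of that list was -0.17 and its mean 0.14.

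The lists of ribosomal proteins and of histidine synthesis were called as shifted downwards at the preset correlation, but not with an estimated correlation. Single genes of purine synthesis and glutamine metabolism fell. Of 51 ribosomal protein genes 10 fell and 0 rose (11 adjusted over the list alone), and the list shifted downwards (camera adjusted p = 0.0029; adjusted p = 0.360 with an estimated correlation; adjusted p = 0.143 with scaling of the log ratios). Of the 41 not called, 11 were printed in the area without signal on 4 arrays. SMU.2015 (L5) fell 1.71-fold, SMU.2018 (S17) 1.68-fold and SMU.2019 (L29) 1.62-fold. These calls were lost in 6, 4 and 5 of 27 alternatives. On 3 arrays for SMU.2015 and 1 array for SMU.2019 every spot held saturated pixels. Of 14 genes in the histidine synthesis list 5 fell and 0 rose (10 adjusted over the list alone; camera adjusted p = 0.0033; adjusted p = 0.129 with an estimated correlation; adjusted p = 0.091 with scaling of the log ratios and 0.186 with the sample channel alone), with SMU.1272 1.49-fold, SMU.1267c 1.46-fold and SMU.1266 (HisH) 1.43-fold lower. These calls were lost in 10, 8 and 4 of 27 alternatives. SMU.1272 encodes the histidyl-tRNA synthetase, which charges tRNA rather than making histidine, and SMU.1267c a hypothetical protein. SMU.2019 and SMU.1267c had the opposite sign in the sample channel alone, and SMU.1267c was above the empty spots on 3 of 4 anaerobic arrays. In purine synthesis 3 of 10 genes fell (4 adjusted over the list alone), namely SMU.32 (purF, 1.58-fold), SMU.35 (purN, 1.57-fold) and SMU.34 (purM, 1.34-fold). That list was not called by camera (camera adjusted p = 0.157; adjusted p = 0.480 with an estimated correlation), but fry called it downwards (fry adjusted p = 0.019). In glutamine and glutamate metabolism 3 of 5 genes fell (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.159; adjusted p = 0.480 with an estimated correlation): the repressor SMU.363 (glnR, 1.52-fold), the glutamate synthase subunit SMU.366 (1.51-fold) and glutamine synthetase SMU.364 (1.34-fold). Fry called the glutamine and glutamate list downwards (fry adjusted p = 0.0079). Of 27 alternatives, 12, 13 and 9 ended the calls of SMU.32, SMU.35 and SMU.34, and 15 and 5 those of SMU.364 and SMU.366.

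In the CRISPR-associated list, all annotated as hypothetical proteins, 3 of 18 genes rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.043; adjusted p = 0.129 with an estimated correlation; adjusted p = 0.055 with the file layout as a block; 9 of 29 alternatives ended the call, at up to 0.363). SMU.1758c rose 1.91-fold and SMU.1754c 1.64-fold, and SMU.1400c fell 1.58-fold (a call lost in 5 of 27 alternatives). In fatty acid synthesis 1 of 13 genes rose, the regulator SMU.1745c (1.32-fold; camera adjusted p = 0.576), and in branched-chain amino acid synthesis 1 of 10 fell, SMU.1384 (leuA, 1.35-fold; camera adjusted p = 0.830). Each of these 2 gene calls was lost in 13 of 27 alternatives. Adjusted over the list alone these became 0 and 1. No limma call was made among 8 genes of the F-type ATPase (camera adjusted p = 0.157), 8 of pyrimidine synthesis (0.344), 7 of malolactic fermentation and agmatine deiminase (0.471) and 16 of the mutanobactin cluster (0.539), nor adjusted over the list alone. With an estimated correlation the adjusted p of these 6 lists lay at 0.785, 0.937, 0.473, 0.746, 0.675 and 0.869, in the order named. With spots without signal left out the F-type ATPase list was called (adjusted p = 0.036; the range over all alternatives was 0.036 to 0.479). Of the 7 genes of malolactic fermentation and agmatine deiminase, 4 were printed in the area without signal on 4 arrays.

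The largest decreases lay mostly outside the lists. The gene SMU.1175, annotated as a sodium and alanine symporter, fell 11.1-fold, but its aerobic values were widely spread (-3.43 ± 1.66, SD, n = 4, against 0.04 ± 0.10, SD, n = 4). Aerobic replicate 1 lay at -1.02 and the other 3 between -4.64 and -3.64. Without it the log2 difference was -4.27, and within the layouts it was -0.99 and -4.34. The genes SMU.758c and SMU.539c (a type IV signal peptidase) fell 3.32-fold and 2.86-fold. SMU.539c was above the empty spots on 1 aerobic and 3 anaerobic arrays, so its fold is not exact, and its call was lost in 14 of 26 alternatives. The nitrogen regulatory protein PII gene SMU.1657c fell 2.76-fold and the ammonium transporter gene SMU.1658 2.65-fold (a call lost in 10 of 27 alternatives), and the glycerol uptake facilitator gene SMU.396 fell 2.56-fold. Aerobic replicate 1 was the aerobic array nearest to the anaerobic mean in all 8 of the largest decreases, and in 112 of the 218 lower and 74 of the 168 higher genes, against 54.5 and 42 by chance. Within the layouts the log2 difference of SMU.1658 was -0.35 and -1.80, that of SMU.1657c -0.76 and -1.75, that of SMU.396 -0.47 and -1.65 and that of SMU.539c -0.27 and -1.90.

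**Figure D3:**
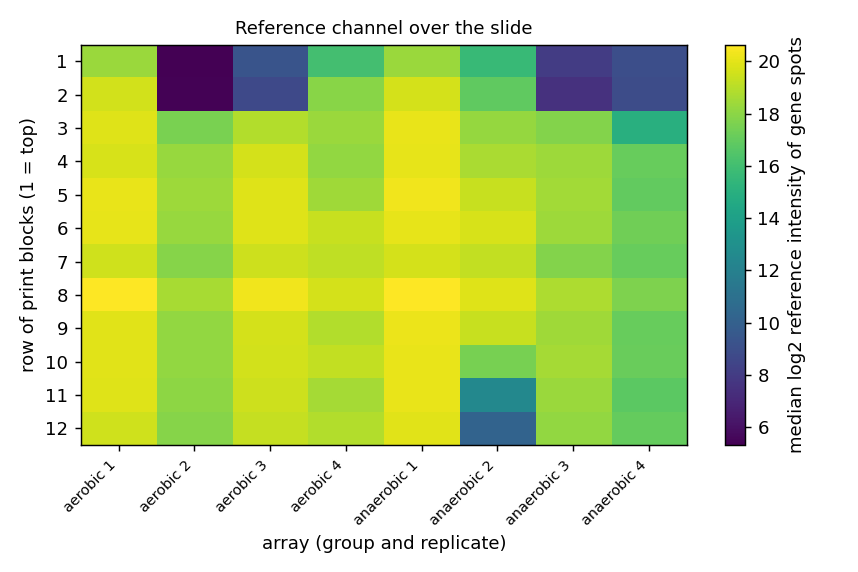
Median log2 reference intensity of the gene spots (colour) in each of the 12 rows of print blocks (vertical axis) on each array (horizontal axis). Rows 1 and 2 are dark on aerobic replicates 2 and 3 and anaerobic replicates 3 and 4, and row 12 is dark on anaerobic replicate 2.

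The arrays differed in where they carried signal. In the top 2 rows of print blocks, with 325 genes, the median reference intensity was not above the empty spots on aerobic replicates 2 and 3 and anaerobic replicates 3 and 4. The same held for the bottom row on anaerobic replicate 2. In the top 2 rows 4.31% of genes were called, against 22.9% elsewhere. With spots without signal left out and 2 arrays per group required, 174 genes were higher and 233 lower. With the top 2 rows left out the counts were 178 and 249. By the reference channel the arrays formed 2 sets, these 4 and the other 4, each with 2 arrays per group. The sets were formed over all gene spots, those of the top 2 rows included. They are therefore no separate evidence of reference batches. Across the 1623 genes outside the top 2 rows, called or not, the differences within the sets correlated at 0.763, and genes are not independent replicates. Fits within the sets called 78 higher and 24 lower genes, and 76 and 51. With the set as a block 161 were higher and 214 lower. As each set held 2 arrays per group, this block bears on the spread and leaves the differences of fully measured genes unchanged. The files also came in 2 layouts. The layout with gene names held 1 aerobic array, which cannot be told apart from its layout there, and 2 anaerobic arrays, and the other held 3 and 2. Across the same 1623 genes the differences within the layouts correlated at 0.712. With the layout as a block 150 genes were higher and 190 lower. Of the 12 called lists, 11 remained called with the layout as a block and 12 with the set. The mean shift of the mutacin list was 2.73 and 3.20 within the sets and 2.70 and 3.08 within the layouts, that of the phosphotransferase list 0.88 and 0.54 and 0.97 and 0.63, and that of the ribosomal proteins -0.29 and -0.37 and -0.25 and -0.44.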

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

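The tests of the genes called lower without loess and of a reference batch were chosen after values bearing on them were seen, as were the alternatives that leave out the area without signal or centre on the median after loess. The other tests in this part were set out before their results were seen.

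In 9 of 166 groups of 4 arrays, 1 array stood far from the other 3, against 8.3 expected by chance. On the log2 ratio to the reference, the aerobic replicate 2 stood apart for SMU.1913c (5.28 against 4.45 to 4.57), SMU.1841 (2.55 against 1.86 to 1.94) and SMU.1596 (2.57 against 1.05 to 1.24). Aerobic replicate 4 stood apart for SMU.2018 (-0.59 against -0.04 to -0.01). Anaerobic replicate 3 stood apart for SMU.1912c (-0.89 against -0.22 to -0.13), SMU.1421 (0.44 against -0.42 to -0.30) and SMU.1517 (1.04 against -0.05 to -0.0026). Anaerobic replicate 4 stood apart for SMU.1516 (0.41 against 0.18 to 0.21). The agreement of the 4 copies of a gene, as the share of the variance of spot log ratios that lies between genes, was 0.896 on aerobic replicate 1 against 0.679 to 0.712 on the other aerobic arrays. On anaerobic replicates 1 to 4 this share was lower, at 0.545, 0.244, 0.323 and 0.212. On anaerobic replicates 2 to 4 most of the variance thus lay between copies of the same gene.

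Few genes were called in the top 2 rows of print blocks. The reference channel had no signal there on 4 arrays, and across the genes of those rows the aerobic minus anaerobic differences of these 4 arrays and of the other 4 correlated at 0.0504, against 0.763 across the other genes, which is consistent with missing hybridisation signal. On the 4 arrays with signal, the SD of the differences in the top 2 rows was 0.799 times that elsewhere (0.598 against 0.748), which leaves open whether the genes printed there also differ somewhat less. Some list genes printed there had differences on the 4 arrays with signal that the 8-array value hides, for example 3.53 for SMU.574c (lrgB, next to lrgA), 2.71 and 2.68 for the glycogen genes SMU.1537 and SMU.1538, and 2.17 for the pyruvate dehydrogenase gene SMU.1422, chosen after their values were seen. Most list genes there differed far less on these arrays, for example 0.02 for SMU.1858 and 0.05 for SMU.2112. SMU.1343c differed in the other direction, at -1.25. No biological explanation was tested.

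With loess per print block and an adjusted p under 0.05 more genes were lower than higher, but not with 1 loess curve, with median centring or, with the same loess, with the replicate block (112 higher, 75 lower), at least 1.5-fold (129 and 102) or limma at an unadjusted p under 0.001 (107 and 70), so the excess depends on threshold and model too. The 218 lower genes had a median difference of -0.57 with loess per block and of -0.53 without loess, which argues against loess having pushed them down as the whole cause. Their median standard error was 1.66 times as large without loess, so a larger spread between arrays may account for calls that end there. The excess of lower calls also depended on centring on the mean, which the strongly raised genes pull up. With the same loess per block and centring on the median, 154 were lower and 191 higher, against 218 and 168 with centring on the mean. A true excess of genes lower in the aerobic cultures stays open, as untested.

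The aerobic arrays lay farther from the 5% CO2 reference than the anaerobic arrays, with SDs of the log ratios over genes of 0.798 ± 0.035 (SD, n = 4) and 0.335 ± 0.051 (SD, n = 4; exact permutation test, two-sided, p = 0.0286, the smallest that 4 against 4 allows). Genes without signal do not account for it, because over the 1181 genes above the empty spots on all arrays the aerobic SD was 2.89 times the anaerobic one. Nor does a smaller dynamic range of the sample channel on the anaerobic arrays, where the SD of log2 intensity was 1.098 times that on the aerobic arrays. A candidate explanation, which was not tested, is that growth without oxygen in the sealed jar left the cells closer to the state of the reference culture. The mean correlation of the reference channels within the groups minus that between them was -0.0101 (0.761 against 0.771). The reference channels as a whole thus did not follow the groups. Pairs of arrays ranged from 0.43 to 0.94, so the test could miss a reference difference in part of the genes. Anaerobic replicate 1, with a reference labelled 0.4, had an SD of the log ratios of 0.284, and the other anaerobic arrays had 0.313 to 0.403. A dye effect that differs between hybridisations stays open, as untested.

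Only 1 of the 35 splits of the arrays into 4 and 4, the real one, called as many genes: 386 against at most 2 in any other split, 168 higher against at most 2 in 1 direction, and 218 lower against at most 2. A share of 1 of 35 is the smallest this test can give. Every other split mixes the groups, which adds the group difference to the spread within a side and makes few calls likely. The splits alone therefore do not exclude chance for the counts of genes. Chance is not excluded for the count of lists either, where the real split called 12, the highest other split called 14, and 3 of the 35 splits gave at least 12 with the preset correlation of camera. The other 2 of these kept 3 aerobic arrays on 1 side, and the 18 splits with 2 aerobic arrays on each side called 0 to 4 lists.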

How the results depend on the processing

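Of 70 named genes past the threshold, none changed sign with another normalization, filter or test except with the sample channel alone, where SMU.80 (1.099), SMU.1267c (0.80), SMU.2019 (0.71) and SMU.2028 (-0.00899) changed sign and the cause was not tested. They stayed past the threshold for 48 of 70 with 1 loess curve per array, 39 with median centring, 49 with scaling, 49 with the authors' values and 8 with the sample channel alone. The counts moved as follows, in the order called, higher and lower. With 1 loess curve they were 164, 106 and 58, with median centring only 131, 104 and 27, with the authors' values 179, 116 and 63, and with the sample channel alone 11, 11 and 0. At an unadjusted p under 0.001 limma gave 177, 107 and 70, and the methods' t-test 163, 95 and 68. Requiring at least 1.5-fold gave 231, with 102 lower, and scaling the log ratios gave 131 lower. With the replicate block 187 genes were called, 112 higher and 75 lower. No array correlated best with its own number, so the numbers are not taken as pairs. Leaving out 1 array gave 266 to 447 called, 124 to 174 higher, 142 to 273 lower (142 without anaerobic replicate 1 and 142 without anaerobic replicate 4, the only arrays to move it by over 1.5 times) and 11 to 12 lists. With an estimated correlation 1 list was called, and with fry 16. Over the alternatives the adjusted p of the mutacin list reached 0.104 and that of the CRISPR list 0.363. The cause of these moves was tested only as far as the normalization is weighed above. Signal limits the genes in the top 2 rows of blocks to 2 arrays per group. The median difference over all genes was -0.09, and 0.01 with median centring only.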

Other observations

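The genes named in the first 2 paragraphs were chosen after their values were seen. The test of neighbouring genes was set out before its result.

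Adjacent genes of a transporter annotated for ferrichrome, an iron carrier, were higher in aerobic cultures. SMU.998, the binding protein, had a log2 difference of 2.95 ± 0.12 (SE), SMU.997 of 2.58 ± 0.11 (SE), SMU.995 of 2.53 ± 0.15 (SE) and SMU.996 of 2.46 ± 0.12 (SE), with adjusted p-values of at most 1.1e-05. The oxidoreductase gene SMU.180, annotated as a possible fumarate reductase, and its neighbour SMU.179 rose by 2.48 ± 0.23 (SE) and 2.46 ± 0.12 (SE). SMU.1088, annotated as a thiamine biosynthesis lipoprotein, and the adjacent SMU.1089 and SMU.1090 rose 3.56-fold, 2.89-fold and 3.03-fold. The P-type ATPase gene SMU.2057c and the succinate semialdehyde dehydrogenase gene SMU.2127 each rose by 2.98, and SMU.1591, which encodes the catabolite control protein CcpA, a global regulator of sugar use, rose by 1.38 ± 0.25 (SE, adjusted p = 0.0068).

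Genes of a different kind were lower. The activating protein SMU.2071 and the anaerobic ribonucleotide reductase SMU.2074, which makes DNA precursors without oxygen, had log2 differences of -0.73 ± 0.12 (SE, adjusted p = 0.0046) and -0.68 ± 0.16 (SE, adjusted p = 0.022). Genes of an amino acid transporter, SMU.1519, SMU.1521 and SMU.1522, had differences of -0.82, -0.71 and -0.81. With 1 loess curve per array SMU.2074, SMU.1521 and SMU.1522 were no longer past the threshold (log2 differences -0.60, -0.42 and -0.63). The same held for these genes with median centring only and with the authors' values. With scaling of the log ratios SMU.2074 also lost its call (limma adjusted p = 0.080). SMU.2071 and SMU.1519 stayed past the threshold in each of these alternatives. The bacteriocin precursor gene SMU.299c fell by 1.04 on the log2 scale, in contrast to the mutacin genes.

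Neighbouring genes differed together. Across 1751 pairs of genes with adjacent locus tags the log2 differences correlated at 0.561, while the highest of 1000 random orders gave 0.089. This is consistent with genes of shared transcripts changing together, although pairs of genes are not independent replicates.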
